A study of Drosophila melanogaster with 72 samples.

How the data were processed

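RNA levels were measured in 72 libraries of Oregon R male flies: 32 labelled head, 32 labelled periphery (the body without the head) and 8 labelled heart. Flies fed ad libitum (ALF) were compared with flies under time-restricted feeding (TRF). Ages were 3, 5 and 7 weeks, with ZT00, ZT06, ZT12 and ZT18 sampled in every group and every 3 h in head and periphery at week 5. Each combination of tissue, week, feeding and ZT had 1 library, so there were no replicates in the strict sense, and libraries of the same week and ZT served as pairs. Per the labels, the libraries were unstranded and made from polyA+ RNA.

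The values analysed were FPKM, as computed by the authors and deposited for 29260 RefSeq transcripts in all 72 libraries. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.2.0c and HOMER were used with genome build dm3; the notes do not state what each tool did. Of 15240 genes, 5900 had several transcripts, and each gene was represented by its transcript with the highest mean FPKM. Low FPKM values multiplied by transcript length fell on evenly spaced steps, which gave each library's total reads: 0.419 to 23.6 M (1e6 reads). With those totals, 100% of the low values checked were whole reads within 0.03 reads. Depth by group, in M reads, was 1.20 to 2.29 (head week 3 ALF), 0.419 to 1.77 (head week 3 TRF), 2.06 to 18.6 (head week 5 ALF), 7.27 to 17.1 (head week 5 TRF), 2.09 to 7.81 (head week 7 ALF) and 1.10 to 13.0 (head week 7 TRF). In periphery it was 4.45 to 12.2 and 6.00 to 11.9 at week 3, 8.39 to 15.1 and 6.49 to 21.7 at week 5, and 4.26 to 15.8 and 2.78 to 11.1 at week 7 (ALF, then TRF); in heart it was 15.2 to 23.6 (ALF) and 7.75 to 19.8 (TRF).

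Tests used limma 3.58.1 in R 4.3.3 (trended empirical Bayes) on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over a tissue's libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. TRF was compared with ALF within each tissue and week, with week and ZT as blocks. All weeks of a tissue shared a common estimate of each gene's spread. Week 7 was compared with week 3 within each feeding type over ZT00, ZT06, ZT12 and ZT18, with feeding and ZT as blocks, and the TRF effects of the 2 weeks were compared as an interaction. The labels give no batch, so a difference between weeks can be confounded with batch. Rhythms of 24 h were tested by moderated F tests of a cosine and sine term, per feeding type in head and periphery at week 5 and over both feeding types in heart. Changes given below are differences of mean log2(FPKM + 1) with their standard error (SE), and group means are FPKM ± SD over n libraries. Where a pair was incomplete, the change came from complete pairs while the group means used every library, so the 2 can differ in size. Correlations between libraries, permutation tests and figures used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

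Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data; lists with at least 4 tested members were tested. Not found by symbol were Hsl and CPT2 (fatty acid oxidation), AkhR and srl (insulin and fasting response), oho23B (ribosomal proteins), ProsMA5 and Dox-A2 (proteasome), NimC1 (hemocyte markers) and SP (male accessory gland markers). The pattern for accessory gland genes took every symbol that starts with Acp, including genes of unrelated function such as Acp1. The list of mitochondrially encoded genes had 0 members among the transcripts and could not be tested. TRiC chaperonin and oxidative phosphorylation are topics of the study, so their lists are not independent evidence.

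Tissue markers of 12 libraries contradicted the tissue label. Every comparison was therefore run as labelled, as planned, and again without these 12; the second fit, and its use for most named genes, was chosen after the data were seen. Labels were never changed. Named genes followed a rule set in advance: among genes past the threshold and changed the same way in every pair, the 10 largest rises and 10 largest falls (week 5, and age in ALF) or the 5 and 5 (other comparisons); where none passed, the 5 and 5 with the smallest unadjusted p, given as values that did not pass; for rhythms the 10 with the largest amplitude, or the 10 with the smallest p where none passed. Members of the clock and TRiC lists and list members past the threshold were also allowed. Alternatives were pseudocounts of 0.1 and 5, no filter on low values and a minimum of 5 FPKM, rescaling by the median of ratios, quantile normalization, robust variance estimates, no pairing, each week fitted alone and leaving out each ZT in turn. Added after the data were seen were the fits without the 12 libraries, list tests without each ZT, list differences per pair, labels exchanged jointly in all tissues and limma-voom on the whole reads recovered from FPKM. The list tests without each ZT used the preset correlation only. The code was tested on simulated data with 200 changed genes per fit. Noise was drawn independently for each gene, without the structure that real libraries share, so the shares recovered need not hold for the data. In the fits without the 12 libraries, changes of 1 and 2 log2 units were recovered for 39.5% and 94.5% of genes in head at week 3, 58% and 95% at week 5 and 0% and 73.5% at week 7. In periphery the shares were 75.5% and 96% at week 3, 96% and 99.5% at week 5 and 80.5% and 95.5% at week 7; in heart, where no library was left out, they were 54% and 86.5%.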

Results

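Eye and body transcripts separated head from periphery, but in 12 libraries they contradicted the label. ninaE, which encodes the rhodopsin of the outer photoreceptors (CG4550), was listed at 9856 to 27051 FPKM in 26 libraries labelled head and at 0 to 0.633 FPKM in 26 labelled periphery. In the other 6 libraries labelled head it was 0.081 to 0.923 FPKM, beside 69.7 to 146 FPKM of the seminal fluid gene Acp36DE and 354 to 733 FPKM of the sperm gene Mst87F. In the other 6 labelled periphery ninaE was 14968 to 22940 FPKM and Acp36DE at most 0.03 FPKM. Body transcripts marked the libraries labelled head at week 5 ALF ZT06, TRF ZT06 and TRF ZT09 and at week 7 ALF ZT12, TRF ZT12 and TRF ZT18. Eye transcripts marked those labelled periphery at weeks 3 and 7 at ALF ZT00, TRF ZT00 and TRF ZT06. Hand, a transcription factor of heart cells, was 721 to 1779 FPKM in the 8 heart libraries, and none of these contradicted its label. The 12 libraries leave 4, 6 and 2 complete pairs in head at weeks 3, 5 and 7, and 2, 8 and 2 in periphery. Results below come from the 60 other libraries where not stated otherwise, with the counts for all libraries as labelled beside them. Clock genes also put the labelled ZTs of TRF libraries at weeks 3 and 7 in doubt (below), on which the pairing at those weeks rests.

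**Figure D1:**
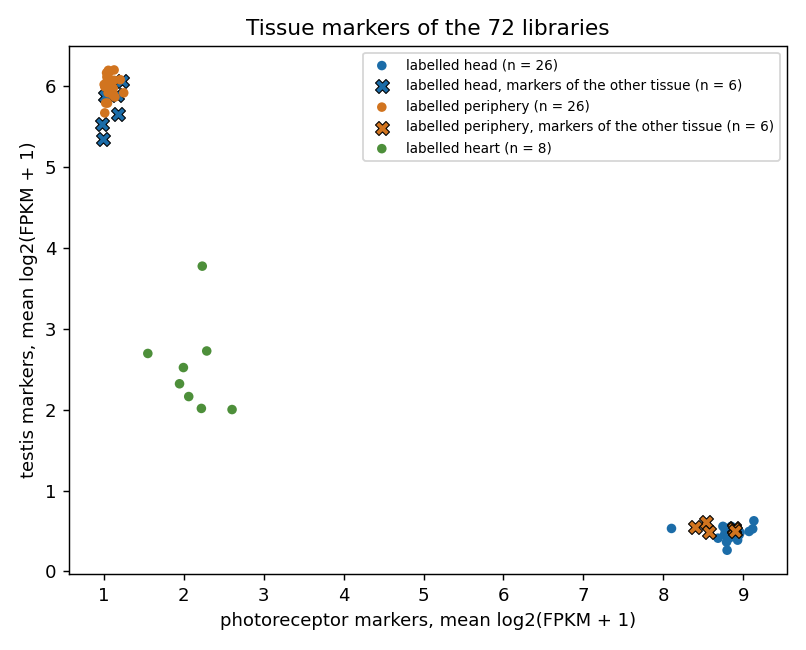
Mean log2(FPKM + 1) of photoreceptor markers against testis markers in the 72 libraries; crosses mark the 12 libraries whose markers contradict the tissue label.

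In heads at week 5, antimicrobial peptide genes were listed higher under TRF as a group at the preset correlation, and no single gene passed. Attacin B (AttB, CG18372, NM_079022, chromosome 2R, 10636728 to 10637580), an antibacterial peptide, was at 18.4 ± 20.2 FPKM in ALF (n = 7) and 243 ± 201 FPKM in TRF (n = 6), a difference of 3.95 (SE 1.05, adjusted p = 0.906). Cecropin C (CecC) differed by 3.67 (SE 0.93) and was higher in 6 of 6 pairs, AttD by 2.44 and the peptidoglycan-degrading PGRP-SC2 by 2.56 (both in 5 of 6 pairs). The lysosomal galactosidase gene Ect3 was at 19.1 ± 4.81 FPKM in ALF and 40.7 ± 14.9 FPKM in TRF (difference 0.97, SE 0.20, higher in 6 of 6 pairs). AttB and CecC have close copies, whose shared reads are not told apart. Lower under TRF were the calcium-binding troponin C genes TpnC47D (-0.72) and TpnC41C (-0.56), each in 6 of 6 pairs, the cuticle gene Cpr11B (-0.78) and the overlapping genes Cks85A (-0.96) and CG8112 (-1.01), which unstranded reads do not tell apart.

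Of 25 antimicrobial and immune recognition genes tested in heads at week 5, 0 passed over all genes, 24 lay above 0 and 15 were higher in TRF when adjusted over the list alone. Their median change was 2.10, and camera called the list higher (adjusted p = 1.17e-19; p = 0.0263 and adjusted p = 0.345 with an estimated correlation). Camera called 11 lists in all, of which none held with an estimated correlation (adjusted p 0.345 to 0.617). Higher besides were the TRiC chaperonin that folds actin and tubulin (median 0.28, 8 of 8 above 0), neuron markers (0.22), hemocyte markers (0.21) and photoreceptor markers (0.15). Lower were ribosomal proteins (-0.25, 85 of 86 below 0), respiratory complex I (-0.30, 33 of 33) and complexes II to V (-0.32, 34 of 35), detoxification (-0.16), fatty acid oxidation (-0.13) and proteasome (-0.04); none of their members passed over all genes or when adjusted over the list alone. Most of these differences came from the pair of ZT15, where the ALF library stood apart in complex I (mean 8.24, next ALF library of the fit 7.13): ribosomal proteins differed by -1.31 in that pair and by -0.0077 on average in the other 5. Without ZT15, ribosomal proteins (median -0.01, adjusted p = 0.759), TRiC (0.06, 0.299), neuron (0.02, 0.581) and photoreceptor markers (0.04, 0.0892), detoxification (0.01, 0.423) and proteasome (-0.02, 0.977) had no call. Complex I (-0.09, adjusted p = 1.52e-05), complexes II to V (-0.10, adjusted p = 2.39e-06) and immune genes (2.23, adjusted p = 8.58e-56) kept theirs at the preset correlation. So did hemocyte markers (0.28) and fatty acid oxidation (-0.22), which lost theirs without ZT21 (adjusted p = 0.0948 and 0.197). The median correlation between immune genes over libraries, with group means removed, was 0.494, far above the preset 0.01. A kept call thus does not offset the loss of all 11 calls with an estimated correlation. TRiC and respiration are topics of the study, so these calls are not independent evidence. Limma called 0 of 9879 genes, and voom called 0. An unadjusted p under 0.05 was found for 140, where chance gives 494. A count that chance gives is, here and below, 0.05 of the genes tested. Exchanged labels can give other counts: other splits that part every pair reached at most 265 in this comparison. As labelled, limma and voom called 0, with 200 and 363 genes under an unadjusted p of 0.05.

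In heads at week 3, a small nucleolar RNA and a pair of uncharacterized genes were lower under TRF in the fit as labelled, in which these libraries all matched their tissue. snoRNA:Me18S-C1831 (CR33674, NR_002508, 2L, 4457603 to 4457674) was at 13.6 ± 6.73 FPKM in ALF and listed at 0 in all TRF libraries (n = 4 each, adjusted p = 0.0237). CG13689 (NM_134694, 2L, 602813 to 603562) fell by 2.21 (SE 0.35), from 8.32 ± 3.15 to 1.42 ± 1.95 FPKM, and CG34213 (NM_001103969, 2R, 19854647 to 19855239) fell by 2.15 (SE 0.33), from 8.53 ± 2.80 to 1.70 ± 2.21 FPKM, each with adjusted p = 0.0344 and in 4 of 4 pairs. These levels amount to few reads: the TRF libraries hold 0.419 to 1.77 M reads. In the fit without the 12 libraries none passed (smallest adjusted p = 0.0801). Highest among the rest, without passing, were CG34291 (listed at 0 in ALF; 13.5 ± 18.6 FPKM in TRF), CR44121, the nuclear receptor gene Hr83 (1.57), CG12259 (0.85) and msd5 (1.28); lowest were CG6232 (-1.30) and the odorant receptor gene Or43b (-1.14). Of 25 immune genes 0 passed, also when adjusted over the list alone, and 23 lay above 0 (median 0.83, camera adjusted p = 1.69e-05, and 0.932 with an estimated correlation); without ZT00 the median was 0.34 and the call was lost (adjusted p = 0.416). Limma called 3 genes as labelled, all lower (659 under an unadjusted p of 0.05), and 0 in the fit without the 12 (750); voom called 0 in both.

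In heads at week 7, with 2 complete pairs, the storage protein gene Lsp2 was at 87.1 ± 110 FPKM in ALF (n = 3) and 2050 ± 955 FPKM in TRF (n = 2), a difference of 5.09 (SE 1.19, adjusted p = 1). Lsp1beta, also made in fat body, differed by 2.91, and CG15739 by 1.09; snoRNA:tra2-a (2.61) and snoRNA:Me28S-G3255b (2.61) were also higher in 2 of 2 pairs. Lower were CG3568 (-1.33), CR43651 (-1.84), CG17777 (-2.20), CG14636 (-1.32) and CG9150 (-3.33). Camera called the fat body markers higher (5 of 5 above 0, median 0.30, adjusted p = 0.00197, and 0.235 with an estimated correlation); 0 of 5 passed over all genes and 1 when adjusted over the list alone. Limma called 0 genes (310 under an unadjusted p of 0.05) and voom 0 (212); as labelled both called 0, with 595 and 969.

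In periphery at week 5, fitted with the tissue's libraries as labelled, no single gene passed with TRF in 8 pairs that all matched their tissue. Camera called the list of digestive proteases lower at the preset correlation only. The spread in this fit was estimated over all weeks, including the 6 periphery libraries with head markers at weeks 3 and 7. The SE and adjusted p below therefore carry tissue differences of those weeks. Simulated changes of 1 and 2 log2 units were recovered for 72% and 91% of genes in this fit. Jheh1, a juvenile hormone epoxide hydrolase (CG15101, NM_137541, 2R, 14740939 to 14742614), was at 95.5 ± 29.4 FPKM in ALF and 59.9 ± 11.2 FPKM in TRF (n = 8 each; -0.63, SE 0.16, lower in 8 of 8 pairs, adjusted p = 1). The cytochrome P450 gene Cyp6a8 differed by -1.05 (SE 0.29, lower in 7 of 8), the odorant-binding Obp93a by -0.39 (8 of 8), CG9360 by -0.47 and CG43861 by -0.22. CG34213, lower in heads at week 3, was higher in 8 of 8 pairs here (0.50, SE 0.14), as in 7 of 8 were CG34446 (0.55), Cyp304a1 (0.48) and CG4558 (0.29), and in 6 of 8 snoRNA:Psi18S-301 (0.78).

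In the same fit camera called 7 lists lower. They were digestive proteases (median -0.32, 23 of 24 below 0), fatty acid oxidation (-0.14), complexes II to V (-0.06), complex I (-0.04), detoxification (-0.04), glycolysis (-0.07) and fat body markers (-0.19). None of their members passed over all genes or when adjusted over the list alone. With an estimated correlation the adjusted p was 0.0892 for detoxification and 0.221 to 0.763 for the other lists. In the fit without the 12 libraries the same medians gave calls for proteases (adjusted p = 5.92e-10), complexes II to V, fatty acid oxidation and detoxification; 3 proteases were lower when adjusted over the list alone, and for detoxification 1 was higher and 3 lower. No call held with an estimated correlation (adjusted p 0.223 to 0.692). Single pairs weighed heavily: the mean difference of complexes II to V went from -0.05 to -0.01 without ZT09 (4 of the other 7 pairs above 0), that of complex I from -0.04 to -0.0021 (5 of 7 above 0) and that of fatty acid oxidation from -0.14 to -0.06 without ZT00. In the fit without the 12 libraries, complexes II to V and detoxification lost their calls without ZT09 (adjusted p = 0.786 and 0.117) and fatty acid oxidation without ZT00 (0.184), and proteases kept theirs whichever ZT was left out. Immune genes were higher in 3 of 8 pairs (mean difference -0.097 ± 1.2 SD, exact permutation p = 0.805). Limma called 0 of 12342 genes as labelled (131 under an unadjusted p of 0.05, where chance gives 617) and 0 without the 12 (629 against 600, smallest adjusted p = 0.262); voom called 0 in both.

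In periphery at week 3, with 2 complete pairs, no single gene passed with TRF, and camera called 9 lists, 8 of them lower. The TRiC chaperonin list had a median of -0.43 (8 of 8 below 0), but it rested on 1 pair: the mean difference was -0.77 at ZT12 and -0.10 at ZT18, and without ZT12 the call was lost (adjusted p = 0.264). The proteasome list had a median of -0.18 (29 of 29), with a mean of -0.32 at ZT18 and -0.02 at ZT12, and lost its call without ZT18 (adjusted p = 0.764), as did complex I, complexes II to V, sarcomere and ovary markers. Lower were complex I (-0.13), complexes II to V (-0.14), glycolysis (-0.24), ribosomal proteins (-0.09), sarcomere (-0.12) and ovary markers (-0.34); photoreceptor markers were higher (0.21). Of these lists no member passed over all genes, and 1 ovary marker was lower when adjusted over the list alone. With an estimated correlation the adjusted p was 0.356 to 0.867, and the TRiC and respiration lists are again not independent evidence. The pairs follow the labelled ZT, which clock genes put in doubt for TRF at this week. TRiC means were 5.48 and 5.91 in TRF at ZT12 and ZT18, and 5.18, 6.25 and 6.01 in ALF at ZT06, ZT12 and ZT18. With TRF times 6 h earlier the 2 pairs would differ in opposite directions. Among single genes, GstD8, a glutathione transferase (0.87, SE 0.19, adjusted p = 0.754), CG9932 (0.50), the phosphodiesterase gene dnc (0.71), a small non-messenger RNA (CR33789, 3.03) and snoRNA:Me18S-G642 (1.42) were highest by p. Lowest were the aldose reductase relative CG6084 (-0.83), the mitochondrial ribosomal protein genes mRpL11 (-0.76) and mRpS35 (-0.47), CG15881 (-0.75) and CG15766 (-0.79). Limma called 0 genes (744 under an unadjusted p of 0.05) and voom 0 (711); as labelled both called 0, with 528 and 777.

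In periphery at week 7, the maltase gene Mal-A1 rose under TRF and the seminal fluid genes Acp32CD and lectin-46Ca fell, in 2 complete pairs. Limma called 20 genes, 14 higher and 6 lower, all in the same direction in 2 of 2 pairs. The count depends on pairing by labelled ZT, which clock genes put in doubt for TRF at this week: it was 2 with no pairing, and 0 without ZT12 or without ZT18. Mal-A1 rose by 1.16 (SE 0.18, adjusted p = 0.0403), from 1268 ± 546 FPKM in ALF (n = 3) to 2145 ± 423 in TRF (n = 2). GstD8 (CG4421, NM_080177, 3R, 8205745 to 8206537) rose by 1.65 (SE 0.19, adjusted p = 0.0191), the lipase gene Lip3 (CG8823, 3R, 9195962 to 9197626) by 2.16 (SE 0.36, adjusted p = 0.0484), from 1.83 ± 1.69 to 7.22 ± 1.27 FPKM, CG34040 by 3.00, and the neighbouring protease inhibitor genes CG16704 and CG16713 by 1.64 and 1.57. Acp32CD (CG4605, NM_057980, 2L, 11015642 to 11016571) fell by 0.92 (SE 0.14, adjusted p = 0.0362). lectin-46Ca (CG1656, NM_144376, 2R, 5704805 to 5706040), fell by 0.9985 (SE 0.17, adjusted p = 0.0484). Acp32CD was at 259 ± 36.0 FPKM in ALF and 141 ± 10.3 in TRF, and CG9029, CG30272 and CG4830 fell by 0.81, 3.33 and 2.87. Voom called 23 genes, 17 of them shared. As labelled, limma and voom called 0, with 1166 and 1001 genes under an unadjusted p of 0.05.

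Of 13 carbohydrate digestion genes at week 7, 12 lay above 0 (median 0.88). At ZT12 and ZT18 the list mean was 7.07 and 6.57 in ALF, against 7.60 and 7.87 in ALF at week 5. In TRF it was 7.65 and 7.57, against 7.75 and 7.84 at week 5. The difference at week 7 thus goes with low levels in the ALF libraries. With TRF times 6 h earlier, the TRF means of 7.65 and 7.57 would be set against 7.37 and 7.07 in ALF. Both differences would keep their direction but be smaller. Mal-A1 passed over all genes, and 9 were higher when adjusted over the list alone; camera called the list higher (adjusted p = 7.92e-13), and the call held with an estimated correlation (adjusted p = 0.0212) and without ZT12 (median 0.93) or ZT18 (0.56), 1 pair remaining in each case. Also called higher were immune genes (median 1.77, 2 of 25 when adjusted over the list alone), detoxification (0.11, 0 of 25), hemocyte markers (0.25, 0 of 4) and the insulin and fasting response (0.15, 1 of 14), and testis markers were called lower (-0.27, 18 of 21 below 0). None of these held with an estimated correlation (adjusted p 0.131 to 0.899), and accessory gland markers had no call. Some rested mostly on ZT12: mean differences there and at ZT18 were 2.42 and 0.61 for immune genes and 0.17 and -0.0007 for detoxification. Without ZT12 immune genes kept their call (median 0.59), while detoxification, hemocyte and testis markers and the insulin and fasting response lost theirs (adjusted p 0.0725 to 0.391).

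In the heart at week 5, antimicrobial peptide genes were listed higher under TRF, and sarcomere and respiratory complex genes lower, as groups at the preset correlation only; no single gene passed in 4 pairs. Diptericin B (DptB, CG10794, NM_079063, 2R, 14754895 to 14755400) was at 799 ± 438 FPKM in ALF and 2899 ± 1913 FPKM in TRF (n = 4 each; difference 1.856, SE 0.22, higher in 4 of 4 pairs, adjusted p = 0.708). CG43109 (1.66) overlaps DptB on the other strand, and its reads are not told apart from those of DptB. Higher in 4 of 4 pairs were also CG42807 (0.91), CG4783 (0.86) and CG43236 (0.97); lower in 4 of 4 were CG7768 (-1.17), CG8329 (-1.18), CG1942 (-0.73) and the ribosomal RNA transcripts CR41544 (-0.62) and CR40640 (-0.61), which share 1 locus. Limma called 0 of 9726 genes (635 under an unadjusted p of 0.05 where chance gives 486), and voom called 0 (900).

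Camera called 14 lists in heart, 7 higher and 7 lower, and none held with an estimated correlation (adjusted p 0.47 to 0.906). Of 25 immune genes 23 lay above 0 (median 1.41), and 8 were higher when adjusted over the list alone. Higher besides were heat shock (0.31, 15 of 15 above 0; 0.11 without ZT06, with the call kept), TRiC (0.17, 8 of 8), detoxification (0.21), carbohydrate digestion (0.28), accessory gland markers (0.38) and ribosomal proteins (median 0.04, mean 0.01). Without ZT12 the medians of the last 2 were -0.14 and -0.02, and the calls were lost for both and for detoxification, carbohydrate digestion and proteasome (-0.07). Sarcomere genes were lower (median -0.45, 23 of 24 below 0), as were complexes II to V (-0.18, 35 of 35), complex I (-0.17, 32 of 33), proteasome (-0.20, 29 of 29), glycolysis (-0.27, 13 of 13), fatty acid oxidation (-0.30) and photoreceptor markers (-0.42). The sarcomere median was -0.24 without ZT12, with the call kept, and fatty acid oxidation lost its call without ZT00, ZT06 or ZT18 (adjusted p 0.264 to 0.413). Apart from the immune list none had members past the threshold when adjusted over the list alone, and none of the 14 had any over all genes. Heart markers had a median of -0.12 (adjusted p = 0.912). Markers of other tissues varied among the 8 heart libraries: the mean log2(FPKM + 1) of accessory gland markers was 1.804 to 3.95 and that of photoreceptor markers 1.55 to 2.61. Lists without a call were clock genes (median 0.01, mean -0.01, adjusted p = 0.859), fatty acid synthesis (-0.08, adjusted p = 0.794), insulin and fasting response (median 0.0068, mean -0.0027, adjusted p = 0.761) and hemocyte markers (median 0.04, mean -0.07, adjusted p = 0.883); 3 ovary markers were too few to test.

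**Figure D2:**
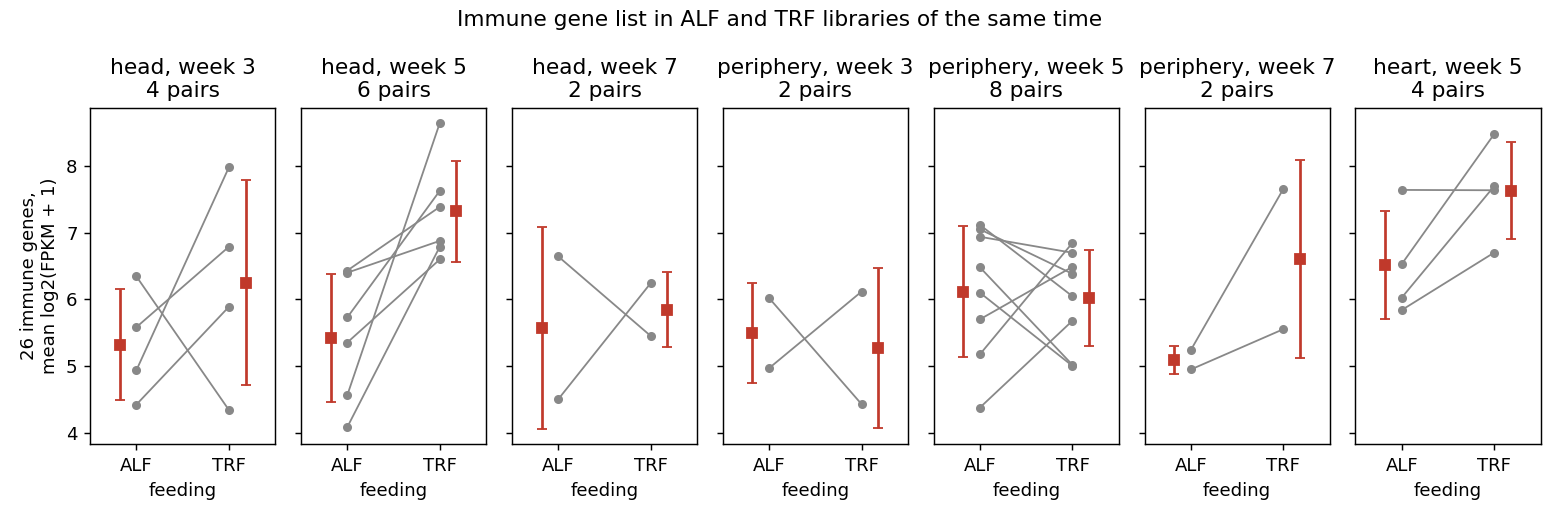
Mean log2(FPKM + 1) of 26 immune genes in ALF and TRF libraries of the same tissue, week and ZT, joined by lines; red squares give the mean ± SD.

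Immune genes as a group were higher under TRF in 19 of 28 pairs over all tissues and weeks, with a mean difference of 0.784 ± 1.52 (SD; permutation p = 0.0108). Pairs of the same week and ZT in different tissues need not be independent. With labels exchanged jointly in all tissues of each of 16 weeks and ZTs the exact permutation p was 0.0178. The immune list was picked for these tests after the list results in the same libraries were seen. Neither p is adjusted for that choice, so they are not independent evidence. Pairs of weeks 3 and 7 also follow labelled ZTs in doubt for TRF. In heads the mean difference was 0.93 at week 3 (3 of 4 pairs higher, exact permutation p = 0.5), 1.897 at week 5 (6 of 6, exact permutation p = 0.0312, the smallest possible; 0.218 adjusted over 7 groups of pairs) and 0.275 at week 7 (1 of 2). In heart it was 1.122 (3 of 4, exact permutation p = 0.25). In periphery it was -0.222 at week 3 (1 of 2) and 1.513 at week 7 (2 of 2). Pearson r between the changes with TRF across all genes, which are not replicates, was 0.262 for head at weeks 3 and 5, -0.042 for weeks 3 and 7 and -0.026 for weeks 5 and 7. In periphery it was 0.116, 0.236 and 0.193, and at week 5 it was -0.014 for head with periphery, 0.209 for head with heart and 0.13 for periphery with heart. Genes with an unadjusted p under 0.05 in both and the same direction numbered 164 for periphery weeks 3 and 7 where 64.4 are expected (36 in opposite directions), 105 for weeks 5 and 7 (48.8; 41 opposite) and 36 for weeks 3 and 5 (19.3; 36 opposite). In heads they numbered 23 for weeks 3 and 5 (4.8; 1 opposite), 20 for weeks 3 and 7 (12.8; 31 opposite) and 1 for weeks 5 and 7 (2.1; 5 opposite), and at week 5 they numbered 32 for head and heart (4.6; 1 opposite), 32 for periphery and heart (16.3; 4 opposite) and 7 for head and periphery (3.8; 1 opposite). No gene passed its test in both members of any of these combinations. Weeks of a tissue share an estimate of spread, so genes with a low estimate can reach p under 0.05 in several weeks together. The expected counts do not allow for this. Weeks 3 and 7 also rest on labelled ZTs in doubt for TRF. A time offset common to both weeks is not told apart from a shared effect of TRF.

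For a difference between the TRF effects of weeks 7 and 3 no single gene passed (limma and voom 0 in both tissues; 1 in each with no filter on low values). In heads 461 genes had an unadjusted p under 0.05 (586 as labelled) and no list was called. In periphery 848 had (216 as labelled), and camera called 9 lists. Carbohydrate digestion differed most firmly: its TRF effect was larger at week 7 by a median of 0.85 (12 of 13 above 0, 0 past over all genes, 6 when adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.0442). The other 8 lists lost their call with an estimated correlation (adjusted p 0.258 to 0.68). These were immune genes (median 1.97, 25 of 25 above 0), glycolysis (0.25), detoxification (0.15, with 1 gene when adjusted over the list alone), proteasome (0.10), ribosomal proteins (0.08), complex I (0.07), complexes II to V (0.06) and testis markers (-0.25). Without ZT12 immune genes (median -0.05), glycolysis (0.09), ribosomal proteins (0.02) and detoxification lost their calls, and without ZT18 so did complex I, proteasome (-0.02), complexes II to V (-0.03) and testis markers.

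Between weeks 3 and 7, the glutathione transferase gene GstD5 and the seminal fluid gene Acp26Ab rose in periphery of ALF flies, in 3 complete pairs. The calcium-binding genes Scp1 and TpnC41C fell. This difference is called age below, although week can be confounded with batch, which the labels do not give. Limma called 28 genes, 24 higher and 4 lower, each in the same direction in 3 of 3 pairs; the count was 270 with no pairing, 0 without ZT06 or without ZT18 and 1 without ZT12. GstD5 (CG12242, NM_080175, 3R, 8201486 to 8202136), rose by 2.13 (SE 0.28, adjusted p = 0.0215), from 5.63 ± 1.04 to 28.7 ± 8.24 FPKM (n = 3 each). The serine protease relative scaf (CG11066, NM_136336, 2R, 1564255 to 1579228) rose by 1.30 (SE 0.11, adjusted p = 0.0102), Acp26Ab (CG9024) by 1.49, from 172 ± 13.3 to 497 ± 139 FPKM, the activity-regulated gene Arc2 by 1.45 and the ribonucleotide reductase gene RnrL by 1.29. CG13386, CG31659, CG6357, Ggt-1 and CG3448 completed the 10 largest rises, with changes of 1.07 to 1.39. Scp1 fell by 1.08 and TpnC41C, a troponin C of muscle, by 1.05, while CG2022 fell by 1.10 and CG9297 by 0.72. Voom called 60 genes, all 28 among them; as labelled, limma and voom called 0, with 219 and 293 under an unadjusted p of 0.05.

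Of 13 carbohydrate digestion genes, 12 lay below 0 with age in ALF periphery (median -0.78), 0 passed over all genes and 9 were lower when adjusted over the list alone. The ALF libraries of week 7 also enter the TRF comparison at week 7, so opposite signs of this list there need no separate change. Fat body markers, without a call (median -0.09, adjusted p = 0.0994), had a mean difference of -0.61 and were lower in 3 of 3 pairs. Camera also called ribosomal proteins (median 0.23, 91 of 93 above 0, 1 when adjusted over the list alone), proteasome (0.36, 29 of 29, 3 when adjusted over the list alone) and TRiC (0.46, 8 of 8) higher, and glycolysis (-0.12) and sarcomere genes (median -0.01, mean -0.09) lower. In the sarcomere list 1 gene, TpnC41C, passed over all genes, and 1 was higher and 3 lower when adjusted over the list alone. The adjusted p of all 6 was 0.825 with an estimated correlation, so none of these calls held. Without ZT06 the calls of TRiC (median 0.27) and proteasome (0.16) were lost, and without ZT18 those of glycolysis (0.0053) and sarcomere genes (0.0018).

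In periphery of TRF flies, 39 genes passed with age, 30 higher and 9 lower, in 2 complete pairs and in the same direction in both; the count was 225 with no pairing, and 0 without ZT12 or without ZT18. CG2022 (NM_141254, 3R, 812222 to 836753), which also fell in ALF, fell by 2.17 (SE 0.16, adjusted p = 0.00281), from 25.9 ± 8.99 to 4.86 ± 1.07 FPKM (n = 2 each). GstD5 rose by 2.19 (SE 0.34, adjusted p = 0.0409) and CG13386 by 1.79, both also called in ALF. CG15239 rose by 3.59 (SE 0.46, adjusted p = 0.0252), from 0.626 ± 0.107 to 18.6 ± 1.30 FPKM, CG4269 by 2.33 and CG14191 by 1.85. lectin-46Ca and CG9029, lower under TRF at week 7, fell by 1.68 and 1.48 with age, which needs no separate change since both comparisons use the TRF libraries of week 7, and CR43633 and CG43788 by 1.88 and 1.70. Of 17 accessory gland genes, Acp26Ab rose by 1.59 and Acp32CD fell by 1.43, 15 did not pass, and when adjusted over the list alone 1 was higher and 3 lower (median -0.53). Camera also called testis markers (-0.20) and digestive proteases (-0.34) lower, and ribosomal proteins (0.32, 91 of 93 above 0), proteasome (0.27, 29 of 29) and immune genes (1.26, 3 when adjusted over the list alone) higher; the adjusted p of all 6 was 0.647 with an estimated correlation. Without ZT12 the medians were -0.38 for immune genes and 0.04 for proteases, and both calls were lost, as were those of accessory gland and testis markers; the proteasome call was lost without ZT18 (median 0.12). Fat body markers had no call (median -0.38, adjusted p = 0.0846) and a mean difference of -0.67, lower in 2 of 2 pairs. Voom called 38 genes, 35 of them shared; as labelled both called 0, with 220 and 204 under an unadjusted p of 0.05.

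In heads no gene passed with age. In ALF, the lens protein gene retinin (CG13057, NM_080256, 3L, 16325033 to 16325889) was at 1065 ± 137 FPKM at week 3 (n = 4) and 582 ± 210 at week 7 (n = 3), a difference of -0.90 (SE 0.14, adjusted p = 0.602). DJ-1alpha differed by -1.41, Cpr49Ag by -1.24, CG14397 by -1.67 and CG10621 by -1.46, and mir-4976 (1.84), CG4630 (1.02), drm (0.81), the replication clamp gene mus209 (1.25) and CG31100 (0.93) were higher. In TRF, Obp19c differed by 1.27, HIP-R by 1.18 and CG3288 by 1.71, dpr2 by -1.20, mir-4971 by -1.91, CG5697 by -3.22, CG15237 by -0.67 and mus209 by -1.36, against its direction in ALF; snoRNA:Me28S-G3255b and snoRNA:Psi28S-3186 were listed at 0 at week 3. The proteasome list was called higher in ALF (median 0.25, 29 of 29 above 0) and ribosomal proteins lower (-0.03); in TRF complexes II to V (0.14) and complex I (0.12) were called higher. None had members past the threshold, also when adjusted over the list alone, and none held with an estimated correlation (adjusted p 0.711 and 0.985 in ALF, 0.803 in TRF). The proteasome median in ALF was 0.14 without ZT06, with the call kept. Ribosomal proteins had a median of 0.09 without ZT00, and complexes II to V and complex I medians of -0.07 and -0.04 without ZT06, with no call. Limma called 0 in ALF (347 under an unadjusted p of 0.05; voom 0, 399) and 0 in TRF (530; voom 0, 325); as labelled, 0 in both (221 and 1219; voom 0, 186 and 1542).

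**Figure D3:**
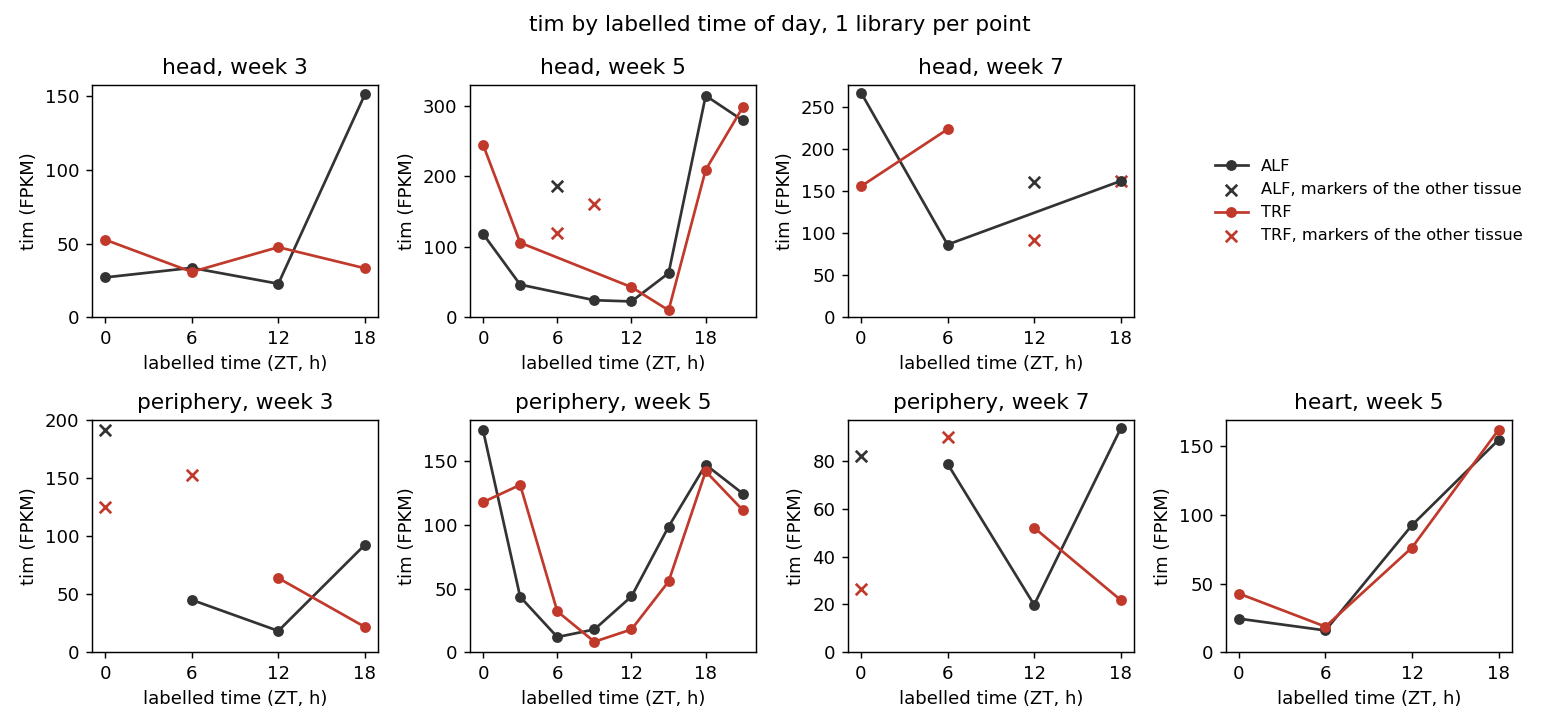
tim (FPKM) by labelled ZT in each tissue and week, ALF and TRF; crosses mark the 12 libraries whose markers contradict the tissue label.

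The clock gene timeless (tim) cycled in heart and periphery at week 5 when adjusted over the clock list alone. The gene period (per) did so in heart and in TRF periphery. Over all genes limma called none, while voom called 3 in heart, tim and per among them. In heart, over 8 libraries of both feeding types, tim (CG3234, NM_001144308, 2L, 3493986 to 3508119) had an amplitude of 1.70 (SE 0.12) and peaked at 16.4 h (adjusted p = 0.0826). It rose from 15.9 FPKM at ZT06 to 155 FPKM at ZT18 in ALF, and from 18.6 to 162 FPKM in TRF. per had an amplitude of 0.99 and peaked at 16.1 h. Over the list alone tim (adjusted p = 0.000169), per (0.000202), Pdp1 (0.00164) and Clk (0.00868) passed in heart. Other genes with the smallest p in heart were CG14630 (amplitude 1.06, peak 3.6 h), CG1942 (1.17, 13.0 h), CG6385 (1.60, 2.2 h), Cbs (0.78, 2.9 h), CG8646 (1.11, 15.5 h), CG17264 (0.54, 1.8 h), CG11796 (1.41, 2.4 h) and CG9577 (0.63, 13.9 h). Limma called 0 genes (1009 under an unadjusted p of 0.05, where chance gives 486), and voom called 3: tim, CG14630 and per.

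In periphery at week 5 as labelled, tim had an amplitude of 1.75 with a peak at 19.7 h in ALF (SE 0.28, adjusted p = 0.183) and of 1.79 with a peak at 21.9 h in TRF (SE 0.28, adjusted p = 0.142). Over the list alone tim passed in ALF (adjusted p = 0.00142; per 0.0579), and tim (0.00113), per (0.019), vri (0.0268) and Clk (0.0332) in TRF. In ALF the pathogen-recognition gene PGRP-SA (0.57, peak 13.3 h) and the antibacterial Def (1.10, 13.4 h), with CG7329, Ance, CG42711, CG42807 and CG12744, were among the genes of smallest p. In TRF these were the mesoderm factor twi (0.46, peak 6.9 h), Drsl2 (1.62, 5.0 h), CG15263 (2.36, 19.2 h), CG6996, snoRNA:Me18S-C1831 and the overlapping CR44052 and CG31414. CG17560 and mir-2494, which lies inside it, had amplitudes of 2.14 and 2.22 in ALF and 2.03 and 2.13 in TRF. Limma called 0 genes in ALF (1210 under an unadjusted p of 0.05) and in TRF (2435), and voom called 0; the feeding types differed in rhythm for 0 genes (606; voom 0, 637).

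In heads at week 5, without the 12 libraries, tim had an amplitude of 2.002 (SE 0.46) and peaked at 20.3 h in ALF, and of 1.97 (SE 0.55) with a peak at 22.7 h in TRF. Over the list alone tim, Clk, cry and jet passed in ALF (adjusted p = 0.0206 each), and per, tim, vri, cry (0.0354 each) and Pdp1 (0.0403) in TRF. The ALF library of ZT15, which stood apart in complex I, weighs on the ALF values. It had Clk listed at 0, and jet (11.2 FPKM) and dco (11.1 FPKM) were also its group's lowest. The calls over the clock list were not repeated without ZT15. Leaving out that time changed the count of rhythms in ALF (below). The glutathione transferase gene GstZ2 was among the genes of smallest p in both, with amplitudes of 1.39 (peak 5.0 h) in ALF and 1.43 (8.6 h) in TRF, as was CG33965 (1.17 and 1.03). In ALF alone these were Sfp33A3, CG15293, Ugt36Bc, Cyp6a22, Rfabg, CG8306, b and CG3348 (amplitudes 0.61 to 2.19). In TRF alone they were CG34134, Ugt35b, CG43094, Cpr49Ag, CG14694, CG32459, Pvf2 and Cpr100A (0.78 to 3.01). Limma and voom called 0 genes in ALF (878 and 849 under an unadjusted p of 0.05) and in TRF (223 and 292, where chance gives 494), and 0 for a difference between them (250 and 288). As labelled, limma called 0 in ALF (730), in TRF (1259) and for the difference (103), while voom called 0, 1285 and 0. In that fit the TRF libraries of the adjacent times ZT06 and ZT09 carry body markers, so its TRF counts mix tissue with time.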

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

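The tests of explanations and the counts for other splits of the libraries were all chosen after the results were seen; the comparison of TRF effects between weeks 3 and 7 was planned, but its fit without the 12 libraries was not.

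A library lay far from the others of its group in 19 of 112 tests (14 groups, 8 measures), where chance flags about 1 in 20 groups. Eye and accessory gland markers account for 8 of them. The mean log2(FPKM + 1) of photoreceptor markers was 1.18 in head week 5 ALF ZT06 (next 8.10) and 1.01 in head week 7 ALF ZT12 (next 8.78), and it was 8.53 in periphery week 3 ALF ZT00 (next 1.13) and 8.88 in periphery week 7 ALF ZT00 (next 1.25). Male accessory gland markers were at 6.48, 6.78, 0.31 and 0.23 in the same libraries, in that order. These are the 4 ALF libraries among the 12; groups that hold a pair of such libraries hide them from this test.

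Several pathway lists also had a library far from its group. Complex I genes had a mean log2(FPKM + 1) of 7.04 in head week 3 TRF ZT12 (next 6.87), 8.24 in head week 5 ALF ZT15 (next 7.48) and 6.96 in periphery week 7 ALF ZT00 (next 7.61). Ribosomal proteins were at 9.38 in head week 3 ALF ZT06 (next 9.33), 9.79 in periphery week 3 TRF ZT06 (next 9.45) and 9.22 in periphery week 7 ALF ZT00 (next 9.73). TRiC genes were lowest at 4.88 in head week 3 ALF ZT06 (next 5.94) and at 5.48 in periphery week 3 TRF ZT12 (next 5.85). Heat shock genes were highest at 4.20 in head week 5 TRF ZT15 (next 3.61) and at 3.91 in periphery week 7 ALF ZT18 (next 3.68). The libraries of periphery week 7 ALF ZT00 and week 3 TRF ZT06 named here are among the 12 and restate the tissue pattern; the next values for complex I in head week 5 and for TRiC in periphery week 3 also come from the 12. The heart library of ALF ZT00 had 15.2 M reads where the next had 22.2 M.

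TRF effects differed between weeks 7 and 3 in periphery for 9 lists by a test of the difference. The median differences of log2 change were 1.97 for immune genes, 0.85 for carbohydrate digestion, 0.25 for glycolysis, 0.15 for detoxification, 0.10 for proteasome, 0.0795 for ribosomal proteins, 0.07 for complex I, 0.065 for complexes II to V and -0.25 for testis markers. Each week has 2 complete pairs, and only carbohydrate digestion kept its call with an estimated correlation (adjusted p = 0.0442). Its levels in the ALF libraries of week 7 were low, and the pairs follow labelled ZTs that clock genes put in doubt for TRF. With TRF times 6 h earlier the difference for this list would be smaller.

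The 12 libraries with markers of the other tissue form the clearest pattern. A mixture of tissues within a library is argued against by genes restricted to the labelled tissue (20 per tissue). Their median level in a library was at most 0.042% of that in the labelled tissue, and single genes can lie above this median. Feeding, age or time of day is argued against as well, since each of these libraries lay at least 12.04 log2 units (eye minus testis markers) from a library of its own group that matched its label, while libraries of a tissue otherwise spread over 1.02. Each of the 12 correlated best with a library of the tissue its markers show (r of at least 0.978, against at most 0.537 with the labelled tissue). Over all weeks 6 labelled head carry body markers and 6 labelled periphery carry head markers. An exchange between head and periphery would have had to cross ages, since at week 3 only libraries labelled periphery and at week 5 only libraries labelled head are among the 12. Those labelled head week 5 were nearest libraries of periphery week 7, and those labelled head week 7 nearest periphery week 3. Those labelled periphery week 7 were nearest head week 5, and those labelled periphery week 3 nearest head week 7 or 5. Whether nearness follows age was not tested, and which library belongs to which label cannot be read from markers.

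Clock genes of TRF libraries at weeks 3 and 7 did not follow their labelled times. An index of per, tim, vri and Pdp1 against cry was set beside its week 5 curve; these tests were revised once after their first values were seen. In all 4 ALF groups the labelled times came nearest the curve (misfit 15.2, and 48.4 with times 6 h earlier, 13 libraries), while in all 4 TRF groups times 6 h earlier came nearest (misfit 13.1, against 43.0 as labelled, 10 libraries). Of the 13.1, 11.5 lay in head week 3 TRF (15.6 as labelled). Its 4 libraries varied little, with an index of -3.03 to -2.02, so the move hardly improves that group. The remaining TRF groups hold 2 libraries each. A delay of the clock by TRF and an exchange of times among TRF libraries cannot be told apart by these values. At week 5, where times are dense, the TRF index lagged ALF by 2.08 h, shorter than 6 h (2.14 h in head, 2.02 h in periphery, 14 pairs, exact permutation p = 0.036, and 0.0312 with both tissues exchanged jointly). No measure of time other than this index was tested at weeks 3 and 7. Low depth is argued against, since the largest counting error of the index was 0.169 log2 units and its SD 0.925. Over the 23 libraries of weeks 3 and 7, r between index and curve was 0.385 (permutation p = 0.0537), rho was 0.303 (permutation p = 0.0949), and r was 0.37 without the 2 libraries farthest from the median of the curve; the SD of the index was 0.532 of that at week 5.

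Immune genes were higher under TRF by a mean of 0.784 log2 units over 28 pairs. This list was picked after the results were seen, and the p-values below are not adjusted for that choice. Depth is argued against, as removing its trend left 0.76 (permutation p = 0.0137, and 0.0218 with the tissues of a week and ZT exchanged jointly), and so are reads shared between paralogs, as 18 genes without near-identical copies gave 0.735 (permutation p = 0.00876, jointly 0.0141). Whether a few libraries decide it stays open. Without the 3 largest pairs the mean was 0.484 (25 pairs, permutation p = 0.0741, jointly 0.105), but leaving out only the largest lowers any mean, so this cannot decide. Leaving out any 1 pair gave 0.661 to 0.887. An effect of feeding stays open as an untested hypothesis, since each combination has 1 library and libraries of the same arm spread by an SD of 0.926.

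Other splits of each comparison's libraries into equal groups, whether or not they part the pairs, asked whether chance can be excluded as the source of a count, where each group had at least 3 paired libraries. Comparisons with 2 complete pairs were not tested in this way, among them the 20 genes of periphery week 7 and the 39 of age in periphery TRF without the 12 libraries. As labelled, at least as many genes as with the real labels came in 13 of 32 splits for head week 3 (3 genes, highest other 55), 57 of 99 for head week 5 (200 at an unadjusted p under 0.05, highest other 2554), 13 of 32 for head week 7 (595; 2815), 19 of 32 for periphery week 3 (528; 5254), 27 of 99 for periphery week 5 (131; 493), 13 of 32 for periphery week 7 (1166; 4733) and 8 of 32 for heart (635; 1205). Without the 12 libraries it held in 19 of 32 for head week 3 (750; 1371), 42 of 98 for head week 5 (140; 2620) and 38 of 100 for periphery week 5 (629; 1827), and for the TRF effect between weeks as labelled in 50 of 86 in head (586; 1528) and 71 of 83 in periphery (216; 6663). Splits that keep pairs together leave fewer pairs to compare, and some call several times more genes than the real labels, which points to structure among the libraries. As labelled, head weeks 5 and 7 and periphery weeks 3 and 7 hold some of the 12 libraries, so tissue is part of that structure there.

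Splits that part every pair are the closer comparison. With these, as many genes came from 40 of 100 for head week 5 (highest other 712), 12 of 32 without the 12 libraries (265), 25 and 36 of 100 for periphery week 5 as labelled and without the 12 (549; 1972), and for the TRF effect between weeks from 21 of 100 in head (780) and 90 of 100 in periphery (3857), so chance cannot be excluded there. With 4 pairs the 8 such splits are too few for a share under 0.05: the highest other was 2 in head week 3 as labelled, 874 without the 12, 507 in head week 7, 1760 and 964 in periphery weeks 3 and 7, and 691 in heart. The real labels gave the most genes in head weeks 3 and 7 and in periphery week 7, all as labelled. In head week 7 the pair of ZT18, and in periphery week 7 that of ZT06, sets libraries of different tissue by their markers against each other. Those 2 counts therefore mix tissue with feeding and cannot be read as an effect of feeding.

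For age, splits that ignore the pairs gave as many genes in 18 of 35 for head ALF (221; highest other 739), 6 of 35 for head TRF (1219; 6118), 16 of 35 for periphery ALF (219; 602) and 18 of 35 for periphery TRF (220; 6073) as labelled. Among the 8 that part every pair the highest others were 352, 1154, 602 and 1613, in the same order, too few splits for a share under 0.05. Without the 12 libraries the 10 splits in ALF are too few as well, with 5 in head (347; 851) and 1 in periphery (28 called genes; 0). For rhythm differences, other splits of the feeding labels gave as many genes in 61 of 100 in head (103; 5933) and 40 of 100 in periphery (606; 1588), and in 24 and 49 of 100 that part every pair (211; 1857), so chance cannot be excluded. For rhythms, other orders of the times gave as many genes in 10 of 100 in head ALF (730; 1641), 22 without the 12 libraries (878; 2601), 24 in head TRF (1259; 2014) and 13 in heart (1009; 1426), so chance is not excluded there. In periphery it is argued against, with 2 of 100 in ALF (1210; 1404) and 1 of 100 in TRF (2435; 2349). In head TRF without the 12 libraries 1 of 100 gave as many (223, highest other 221). The count lies below 0.05 of the genes tested (494), a figure that no other order reached either. The 2 yardsticks disagree, so no conclusion is drawn.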

How the results depend on the processing

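The fits without the 12 libraries, every alternative tried within them, gene lists without each ZT and limma-voom were chosen after the data were seen. The planned count test was not run, since the deposited values are FPKM, and limma-voom on recovered reads took its place; the other alternatives were planned. For named genes of the TRF and age comparisons the direction held under every alternative. They had been chosen for the same direction in every pair or for the smallest p, so a turn was unlikely in advance. Amplitudes of rhythms have no sign and could not turn. Of the results for named genes, 2388 stayed on the same side of the threshold, 167 were no longer past it and 29 newly past it. For a gene that had not passed, the same side means that it again did not pass. For counts of genes 558 results stayed within 1.5 times the reported count and 63 moved; for single lists 707 kept their call, 280 lost it, mostly with an estimated correlation, and 35 reversed. Where nothing else is said, the cause was not tested. Depth limits the head libraries of week 3 most (0.419 to 2.29 M reads), and 2 complete pairs limit week 7 and periphery at week 3.

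In head week 3 as labelled (3 genes) the count was 6 with a pseudocount of 0.1, 1 with 5, 5 with no pairing, and 0 with no filter, median of ratios, quantile normalization, the week fitted alone, voom or without the 12 libraries; without the 12 (0 genes) it was 2 with a pseudocount of 0.1 and 4 with no pairing. Without the 12 libraries head week 7 had 1 gene with a pseudocount of 5 and 14 with no filter, periphery week 3 had 1 with a pseudocount of 0.1 and 1 with no filter, and both interactions and head TRF age had 1, 1 and 4 with no filter. In periphery week 7 the count was 0 as labelled and 20 without the 12; from 20 it went to 12 with no filter, 2 with no pairing and 88 with the week fitted alone. In periphery ALF age it was 0 as labelled and 28 without the 12; from 28 it went to 78 with at least 5 FPKM, 18 with median of ratios, 17 with quantile normalization, 270 with no pairing and 60 with voom. In periphery TRF age it was 0 as labelled and 39 without the 12; from 39 it went to 17, 24 and 225 with median of ratios, quantile normalization and no pairing. Voom called 1285 rhythms in head TRF as labelled and 3 in heart, against 0. The head TRF libraries of the adjacent times ZT06 and ZT09 carry body markers, and without the 12 libraries voom called 0 there.

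With an estimated correlation the count of lists called was 0 in every comparison except periphery week 7 and the periphery interaction without the 12 libraries, each with 1. Without the 12 libraries 1 list was called in head week 7, 4 in periphery week 5, 6 in periphery week 7, 2 in head ALF age and 2 in head TRF age. Within these fits head week 7 had 2 and head ALF age 4 with at least 5 FPKM, head ALF age 4 with median of ratios, and periphery week 5 had 7 with a pseudocount of 0.1. Rescaling by the median of ratios ended the calls of photoreceptor markers in head week 5, sarcomere genes and ovary markers in periphery week 3, detoxification and the fasting response in periphery week 7, detoxification in the periphery interaction, and proteases and accessory gland markers with age in periphery TRF (all without the 12), and of fatty acid oxidation in heart. Leaving out the 12 libraries, which carry the other tissue's RNA, reversed lists called as labelled. Their medians became 0.0533 for testis, 0.15 for photoreceptor and 0.22 for neuron markers (head week 5), -0.0205 and 0.0612 for photoreceptor and neuron markers (head week 7), and -0.0227 and -0.11 for the same (periphery week 7). In periphery week 3 they became -0.14 for immune genes, 0.10 for carbohydrate digestion, -0.0558 for proteases (the direction of the test turned), -0.0906 for ribosomal proteins, 0.0875 for accessory gland and -0.039 for testis markers. With age in head TRF they became 0.0442 for carbohydrate digestion, -0.0478 for proteasome, -0.26 for testis, 0.12 for photoreceptor and 0.13 for neuron markers, and ribosomal proteins reversed to 0.0669 with median of ratios. With age in periphery they became 0.18 for immune genes in ALF, and 0.0917, 0.11 and 0.32 for complex I, complexes II to V and ribosomal proteins in TRF. The r between TRF effects went from 0.205, 0.066 and 0.693 as labelled to 0.262, -0.042 and -0.026 (head weeks 3 and 5, 3 and 7, 5 and 7), from 0.224, 0.871 and 0.28 to 0.116, 0.236 and 0.193 (the same in periphery), from -0.212 to -0.014 (head and periphery, week 5), from -0.029 to 0.209 (head and heart) and from 0.128 to 0.13 (periphery and heart), so 3 changed sign.

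Leaving out each ZT in turn gave 0 to 7 genes in head week 3 as labelled and 0 to 4 without the 12 libraries (highest without ZT06), 0 to 1 in head week 7 and periphery week 3 without the 12, 0 to 1 for the head interaction in both fits, and 0 to 20 in periphery week 7 without the 12 (0 without ZT12 or ZT18, which hold its complete pairs). With age in periphery without the 12 it gave 0 to 28 in ALF (0 without ZT06 or ZT18) and 0 to 39 in TRF (0 without ZT12 or ZT18). For rhythms it gave 0 to 20 in head ALF without the 12 (highest without ZT15), 0 to 2 and 0 to 3 in periphery ALF as labelled and without the 12, 0 to 341 and 0 to 357 in periphery TRF (highest without ZT06), and 0 to 2 for the rhythm difference in periphery in both fits (highest without ZT15). Where a ZT left 1 pair, its libraries were assumed to vary like the other groups. Rescaling moved the median change by more than 0.1 only as labelled: by 0.13 in head week 7 (median of ratios), 0.13 and 0.17 in periphery weeks 3 and 7 (quantile), 0.14 and -0.12 for the head interaction (median of ratios, then quantile), -0.17 in head ALF age (quantile), and 0.16 and -0.28 in head TRF age (in the same order).

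For gene lists, leaving out each ZT in turn gave, without the 12 libraries, 0 to 5 calls in head week 3, 5 to 11 in head week 5, 1 to 6 in head week 7, 9 to 12 in periphery week 3, 4 to 8 in periphery week 5, 2 to 6 in periphery week 7, 1 to 3 and 8 to 10 for the head and periphery interactions, 4 to 8 and 0 to 4 with age in head ALF and TRF, and 5 to 8 and 6 to 7 with age in periphery ALF and TRF. In heart it gave 9 to 14. Lists whose call reversed had medians of -0.11 to -0.0090 (proteasome, head week 5; the direction of the test turned without ZT15), -0.27 to 0.0088 (complexes II to V, periphery week 3; above 0 without ZT18), -0.30 to -0.0389 (proteasome, periphery week 3; the direction of the test turned without ZT18), -0.0168 to 0.0837 (ribosomal proteins, heart; below 0 without ZT12), -0.14 to 0.59 (accessory gland markers, heart; below 0 without ZT12), -0.0915 to 0.0939 (ribosomal proteins, age in head ALF; above 0 without ZT00), and -0.0443 to 0.34 and -0.0678 to 0.33 (complex I and complexes II to V, age in head TRF; below 0 without ZT06). For the periphery interaction they were -0.0313 to 0.12 (complexes II to V) and -0.0174 to 0.22 (proteasome), both below 0 without ZT18, and with age in periphery TRF -0.38 to 3.56 (immune genes) and -0.85 to 0.0411 (proteases), both turned without ZT12.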
